A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

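RNA was taken from 6 splicing-factor mutant strains and WT (strain ED666) of S. pombe after 15 minutes at 37 °C, and poly(A) directional libraries were made from 1 µg of RNA. One table for the whole series was used. Its values are counts per splice junction in each library, spliced and unspliced, per the file headers. STAR 2.5, bedtools 2.26 and the genome build ASM294v2 were used, per the submitters' processing notes. How a read was classed as unspliced, the read length and the annotation used are not given in the sources used here. The authors deposited 14440 junctions in classes of their own naming, of which 5144 were annotated introns, 6512 were called new introns, 1289 used another 3′ splice site, 1144 another 5′ splice site and 351 another pairing of known sites. Unspliced counts above 0 stood only at annotated introns, where 1 unspliced count per intron was given, so that its 5′ and 3′ sides could not be separated.

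Gene symbols and intron numbers came from the NCBI annotation of the reference assembly used here, and sequence features from its sequence. Branch sites are not annotated there and were inferred. Each was taken as the last match to CTRAY (R is A or G, Y is C or T) within the last 60 nt of the intron. No match was found in 554 of the tested introns. Of 5144 annotated introns 5077 matched a reference intron at both ends, in 2403 genes, and 5134 of the 5143 on the 3 chromosomes began with GT and ended in AG. The summed depth of annotated introns ran from 420473 (WT replicate 1) to 1858792 (ntr1), and the median depth of a tested intron from 59.0 reads in WT replicate 1 to 212 in ntr1. Groups were taken from the sample labels. The 2 WT libraries were not 1 library given 2 times, since their totals per intron differed beyond counting error (chi-square 5771 on 2513 degrees of freedom), their log odds had a Spearman correlation of 0.771 across introns, and 12 introns differed between them in Fisher's exact test with BH adjustment.

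The unspliced share of an intron is unspliced over unspliced plus spliced reads. Introns with at least 20 reads in every library were tested, 2514 in all, with lengths from 32 to 855 nt and a median of 62 nt. Log odds used a pseudocount of 0.5. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the spliced and unspliced counts, with 1 coefficient per library and 1 coefficient of unspliced over spliced per group, so that no scaling between libraries enters. It was fitted for each strain against WT in 1 fit of all libraries (1 residual degree of freedom), for the mutants as a class (6) and for each strain against the other 5 mutants (4). In that last fit, as in the first, a lone library is assumed to vary like the others. Adjustment was by BH at 0.05. Library medians were compared with exact permutation tests over the 28 splits of the 8 libraries into 6 and 2, one-sided for overall retention and two-sided elsewhere. Gene totals were tested with edgeR and TMM. Other tools were limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.

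The tests were tried on simulated counts over the 2514 introns with 50 introns changed at each fold. Every library was drawn at the WT shares with a common dispersion, without shifts of whole libraries or a spread between strains. The rates for the class fit and for 1 strain against the others therefore do not carry over to the real mutant libraries. Those of the strain fit hold only if a mutant library varies as the WT pair does, which was not tested. Few introns changed in the simulation while most are called in the real data, where the BH cutoff is therefore looser. The strain fit recovered 10% of changes of 2-fold in the odds, 40% of 4-fold, 94% of 16-fold and 96% of 32-fold, with 0.216% of unchanged introns called. The class fit recovered 18%, 80%, 100% and 100%, with 0.259% of unchanged introns called, and the fit of 1 strain against the others 28%, 76%, 100% and 100%, with 0.432%. For gene totals, simulated over 1363 genes, 100% of 2-fold and 4-fold rises, 92% of falls to 0.5 and 100% of falls to 0.25 were recovered. Of unchanged genes 0.602% were called. These totals were drawn with a dispersion that was set and not estimated from the data, and without a spread between strains. Their rates do not carry over to the real gene totals either.

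The groups, tests, minimum of 20 reads, 9 gene lists (chosen by symbol), 12 fixed genes and a first set of other settings were chosen before the data were examined. The introns named were, among those with at least 50 reads in every library and 1 per gene, the 12 largest rises and the 5 largest falls of the class in percentage points, the 3 largest rises and the largest fall of each strain, the 2 largest differences of a strain from the other mutants, up to 4 per gene list, and all tested introns of the fixed genes; where none passed the same number was taken by size. Genes named for their total reads were chosen after their values were seen. That first set was minimums of 10, 50 and 1 reads, DESeq2, limma on log odds, a 2-fold bound, unspliced counts alone with TMM or DESeq2 size factors of the totals, Fisher's exact test, a pseudocount of 1, means for medians, thinning to 20 reads, and leaving out each library. Centring on library medians, the spread of the WT pair after centring, TMM on unspliced counts, spliced reads alone, unspliced reads divided by intron length, random lists matched on length as well as count, and the references of short gaps were added after the data were seen. Junctions outside the annotated introns were used only for values in the closing section. One of the introns that the naming rule selects in the ribosomal protein list is not reported here.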

Results

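Poly(A) RNA was sequenced from fission yeast, Schizosaccharomyces pombe, carrying temperature-sensitive alleles of splicing factors. The 6 mutant strains, with 1 library each, were prp10-R379H (a subunit of SF3b in the U2 snRNP), sap114-A152V (a subunit of SF3a, also in the U2 snRNP), prp1-G705D (a protein of the U4/U6.U5 tri-snRNP), cwf22-G191D (a component of the assembled spliceosome), prp22-V801M;G917R (the helicase that releases spliced mRNA) and ntr1-W597R (a factor of spliceosome disassembly). The wild type (WT) had 2 libraries. Cultures grown at 25 °C were held at 37 °C for 15 minutes before RNA was extracted. For every annotated intron the table gave the reads spliced across it and the reads counted as unspliced. Over 5144 annotated introns, spliced plus unspliced reads came to 809751 for prp10, 1279618 for prp22, 909213 for cwf22, 1312546 for sap114, 1139031 for prp1, 1858792 for ntr1, and 420473 and 846804 for WT replicates 1 and 2. The tests used the 2514 introns, in 1363 genes, that had at least 20 reads in every library. Coordinates are those of the table, in build ASM294v2, counted from 1. Intervals on shares of a single library are Wilson 95% intervals and cover counting error only. No mutant strain has a second library, and p-values measure a spread between libraries that may be partly technical. For a strain against WT that spread comes from the WT pair alone. For a strain against the other mutants it comes from those other mutants, and for the mutants as a class from all 8 libraries.

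The first comparison asked how much unspliced RNA the mutant strains held after the shift. In the WT libraries the typical intron was almost always removed, with a median unspliced share of 4.67% and 5.60%. In the mutants the median was 37.5% in prp1, 62.4% in prp10, 66.9% in prp22, 67.4% in cwf22, 78.5% in sap114 and 81.1% in ntr1. The mutant medians averaged 65.6% ± 15.6 (SD, n = 6) against 5.13% ± 0.656 (SD, n = 2) in WT, a difference of 60.5 percentage points (one-sided exact permutation test over the 28 splits of the libraries, p = 0.0357, the smallest these splits can give). Shares over summed reads gave 64.9% ± 13.3 (SD, n = 6) and 11.8% ± 0.540 (SD, n = 2), with the same p of 0.0357 in the exact test. More unspliced than spliced reads were found at 88.3% of the introns in ntr1, 31.9% in prp1, and 4.06% and 4.34% in the WT libraries. With either WT library left out only 7 splits remain and the exact p is 0.143, the smallest that design allows.

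**Figure D1:**
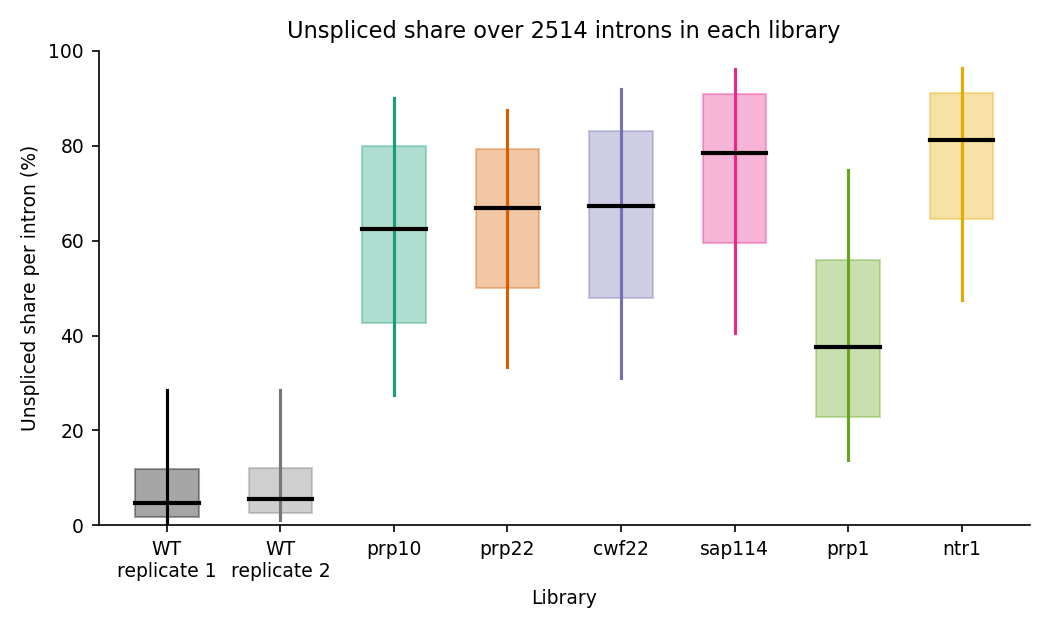
Unspliced share per intron in percent (vertical axis) for each of the 8 libraries (horizontal axis), over 2514 introns. The thick line is the median, the box spans the quartiles and the thin line runs from the lowest to the highest decile. The WT medians are 4.67% and 5.60%, and the mutant medians lie between 37.5% in prp1 and 81.1% in ntr1.

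The second comparison asked which introns changed in the mutants as a class. Retention rose at 2437 of the 2514 introns tested. In intron 3 of cnt5, a regulator of ARF GTPases (SPBC17G9.08C, II 2184099 to 2184222, coding region), the unspliced share went from 5.05% ± 1.70 (SD, n = 2) in WT to 91.5% ± 6.88 (SD, n = 6) in the mutants. Intron 3 of pck1, a protein kinase C (SPAC17G8.14C, I 2367726 to 2367766), went from 7.31% ± 3.76 to 91.2% ± 11.7, and intron 2 of hri2, an eIF2 alpha kinase (SPAC222.07C, I 956185 to 956233), from 5.79% ± 2.46 to 89.2% ± 12.7. Intron 1 of cys11, a cysteine synthase (SPBC36.04, II 848118 to 848262), reached 85.9% ± 14.3, and the long intron 3 of gnd1, phosphogluconate dehydrogenase (SPBC660.16, II 230680 to 231496), reached 88.4% ± 12.5. Intron 1 of gmh4, a galactosyltransferase (SPBC8D2.17, II 1391094 to 1391146), had no unspliced read among 61 and 90 reads in WT and 82.0% ± 15.3 unspliced reads in the mutants.

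By edgeR's quasi-likelihood test on the odds of unspliced to spliced reads, with Benjamini-Hochberg (BH) adjustment over introns, 2437 of 2514 introns rose and 0 fell in the mutants. The rises lay in 1340 of the 1363 genes. No intron fell at an unadjusted p under 0.05 in edgeR (0), nor after adjustment in DESeq2 (0) or limma (0), where 2457 and 2449 rose. Unspliced counts alone, scaled by TMM of totals, gave 2378 rises and 2 falls. The median change was 54.4 percentage points, or 4.94 on the log2 scale of the odds. In 2480 introns all 6 mutant shares lay above both WT shares, where chance gives 3.57%, and in 1 all lay below. The log2 change in the odds was 7.95 for cnt5 intron 3 (standard error 1.16, edgeR adjusted p = 2.3e-06), 7.96 for pck1 intron 3 (standard error 1.16) and 7.75 for hri2 intron 2 (standard error 1.22). The other introns among the 12 largest rises in percentage points were in SPAPB1A10.08 (intron 1, 4.17% to 90.4%), nog1, a GTPase of ribosome assembly (intron 3, 8.61% to 91.2%), dsc5, of a Golgi ubiquitin ligase complex (intron 1, 5.14% to 87.4%), tup12, a transcriptional corepressor (intron 2, 11.6% to 93.4%), SPAC323.04 (intron 2, 4.72% to 86.5%) and vac8, a vacuolar protein (intron 3, 2.66% to 84.5%). Each of these was higher in 6 of 6 mutants.

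Introns that did not pass were often retained in WT already. Of the 77 introns that did not pass, 28 had a WT share above 50%, as did 105 of all 2514. No intron passed as a fall, so the 5 smallest changes are given by size, and none of them passed in edgeR. Intron 2 of dbp2, a DEAD-box helicase (SPBP8B7.16C, II 3663207 to 3663905), was at 99.5% ± 0.0711 (SD, n = 2) in WT and 99.2% ± 0.367 (SD, n = 6) in the mutants, with an edgeR adjusted p of 0.426. Intron 2 of prp10 itself (I 4336556 to 4336621) was at 91.1% ± 3.11 and 94.3% ± 2.66, with an edgeR adjusted p of 0.374. Intron 3 of mug161 (I 636177 to 636233) was at 94.6% ± 2.42 and 97.7% ± 0.688, intron 1 of etp1 (I 5037447 to 5037491) at 93.4% ± 1.69 and 97.4% ± 0.999, and intron 1 of SPAC18B11.09C (I 303232 to 303333) at 92.6% ± 5.93 and 96.0% ± 1.82. When the odds were centred on each library's median, which removes the shift common to all introns, 215 introns rose and 370 fell relative to that median, and unspliced counts alone scaled by TMM on unspliced reads gave 332 and 385.

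**Figure D2:**
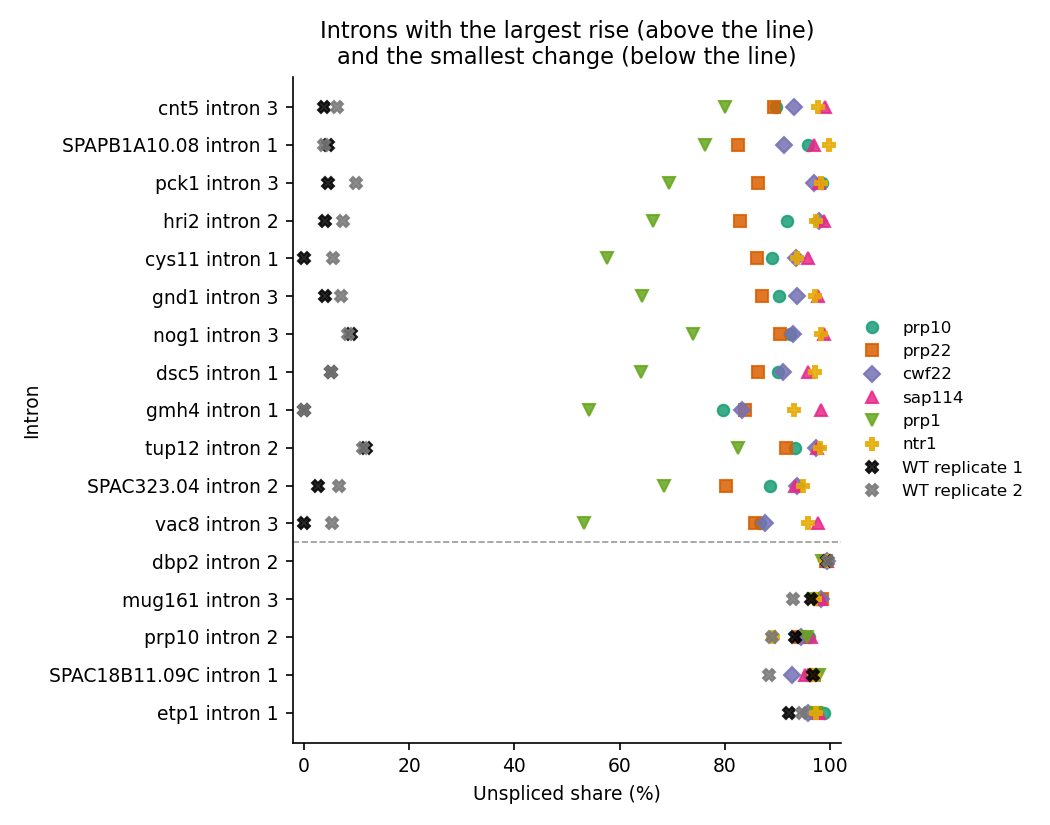
Unspliced share in percent (horizontal axis) in each of the 8 libraries for the 12 introns with the largest rise and the 5 with the smallest change (vertical axis), 1 intron per gene. Points are single libraries. The prp1 library is the lowest mutant at each of the 12 rising introns (54.1% at gmh4 intron 1), and in the 5 introns below the line WT shares already lie between 88.4% and 99.6%.

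The third comparison grouped the introns by 9 gene lists fixed before the data were examined. Introns of ribosomal protein genes and of respiratory chain genes had lower unspliced shares in the mutants than the typical intron, though neither list passed the BH adjustment. Of 88 ribosomal protein introns 84 rose (84 adjusted over the list alone), and their median share was 43.1% in the mutants and 3.36% in WT. Their log2 odds rose by 0.71 less than those of the typical intron (value −0.71, exact permutation p = 0.0357 over 28 splits, BH p = 0.107 over 9 lists). The members with the largest rise, well above the median of the list, were intron 1 of rps1001 (6.91% ± 0.957 to 71.4% ± 17.7), of rpl702 (9.76% ± 2.05 to 72.1% ± 14.9) and of rps502 (11% ± 0.541 to 73.0% ± 13.9), with SD over n = 2 WT and n = 6 mutant libraries. Of 60 introns in genes of the respiratory chain and ATP synthase, 59 rose (59 adjusted over the list alone), with a median of 41.3% in the mutants and 3.24% in WT and a value of −0.71 relative to all introns (exact permutation p = 0.0357, BH p = 0.107). The members with the largest rise, again above the median of the list, were atp1 intron 2 (7.34% ± 2.87 to 80.3% ± 7.81), sdh1 intron 1 (2.79% ± 0.593 to 64.6% ± 16.5), qcr9 intron 1 (10.9% ± 4.15 to 78.0% ± 9.98) and cox6 intron 1 (22.2% ± 4.03 to 78.7% ± 6.33). Among 10000 random lists of introns matched on read count, 0.01% for ribosomal protein genes and 0% for respiratory chain genes had a change as low. The random lists were drawn intron by intron, while introns of one gene resemble each other, so these percentages may be too small. The 60 respiratory chain introns lie in 30 genes and the 88 ribosomal protein introns in 74. Ribosomal protein and respiratory chain introns lay below the median log2 odds of all introns in every one of the 6 mutants, with means of −1.50 and −1.56. They also did so in both WT libraries (−0.85 and −0.74 for ribosomal protein, −0.84 and −0.86 for respiratory chain introns). The chaperone, proteasome and ubiquitin, translation factor and vesicle traffic lists lay below it in each mutant too.

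Introns of meiotic genes had a higher value than the typical intron, but the list did not pass the BH adjustment. Of 21 introns 20 rose (20 adjusted over the list alone), with a median of 70.1% in the mutants, and their odds rose by 0.63 more than the typical intron's (exact permutation p = 0.0357, BH p = 0.107, percentile 92.1 among random lists). The examples were spo14 intron 3 (3.23% ± 2.33 to 82.2% ± 13.5) and spo20 intron 2 (10.2% ± 1.79 to 83.8% ± 13.3), which act in secretion and spore membrane formation, with mug64 intron 1 (8.59% ± 1.39 to 50.4% ± 15.7) and mug161 intron 4 (49.6% ± 4.17 to 76.1% ± 8.91, edgeR adjusted p = 0.0483). The mug161 call was lost without any 1 library other than prp1, and with unspliced counts alone its log2 value was −0.02.

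The other 6 lists did not stand apart from all introns in the exact permutation test. In the cell cycle and cytoskeleton list 83 of 83 introns rose (83 adjusted over the list alone). They included the introns of cam1, calmodulin (intron 1, 7.72% ± 2.21 to 85.2% ± 11.6), suc1, a partner of the Cdc2 kinase (intron 1, 7.94% ± 1.31 to 85.1% ± 10.5), and the GTPase gene rho3 (intron 2, 21.0% ± 5.47 to 94.5% ± 6.27). The list also took in tbp1, the TATA-binding protein, by its symbol (intron 2, 8.05% ± 0.891 to 84.6% ± 16.4). Of 94 introns in spliceosome genes 93 rose (93 adjusted over the list alone), among them cwf29 intron 1 (8.89% ± 3.59 to 85.5% ± 12), cwf2 intron 2 (3.20% ± 2.76 to 79.2% ± 15.8), sap49 intron 1 (1.12% ± 1.59 to 74.9% ± 16) and prp39 intron 6 (2.41% ± 1.31 to 67.8% ± 19.5). Of 98 introns in vesicle traffic genes 97 rose (97 adjusted over the list alone), such as apm1 intron 3 (5.28% ± 2.98 to 83.6% ± 11.5), vps68 intron 2 (13.5% ± 2.12 to 87.4% ± 6.45), ypt3 intron 2 (12.1% ± 1.92 to 85.9% ± 14.4) and vps35 intron 5 (13.1% ± 2.36 to 84.2% ± 11.9). Of 77 proteasome and ubiquitin introns 76 rose (76 adjusted over the list alone), such as ubc6 intron 2 (3.30% ± 3.34 to 73.7% ± 17.9), rpt5 intron 1 (9.36% ± 2.42 to 79.3% ± 17.1), rpt4 intron 1 (17.0% ± 3.59 to 86.3% ± 9.15) and pre5 intron 3 (11.2% ± 3.96 to 80.5% ± 15.5). All 32 translation factor introns rose (32 adjusted over the list alone), such as tif225 intron 3 (2.67% ± 0.511 to 78.7% ± 17.6), sum1 intron 2 (5.34% ± 3.89 to 78.2% ± 12.6), tif308 intron 2 (7.17% ± 4.65 to 76.2% ± 12.5) and sup35 intron 1 (3.79% ± 5.36 to 69.9% ± 13.6). Of 28 chaperone introns 27 rose (27 adjusted over the list alone), such as those of the chaperonin genes cct8 (intron 3, 6.10% ± 1.90 to 71.6% ± 13.4), cct6 (intron 3, 8.84% ± 0.721 to 72.8% ± 13.7) and cct2 (intron 1, 7.49% ± 0.446 to 66.3% ± 13.9) and of cdc37 (intron 3, 12.1% ± 1.07 to 76.1% ± 14.6).

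**Figure D3:**
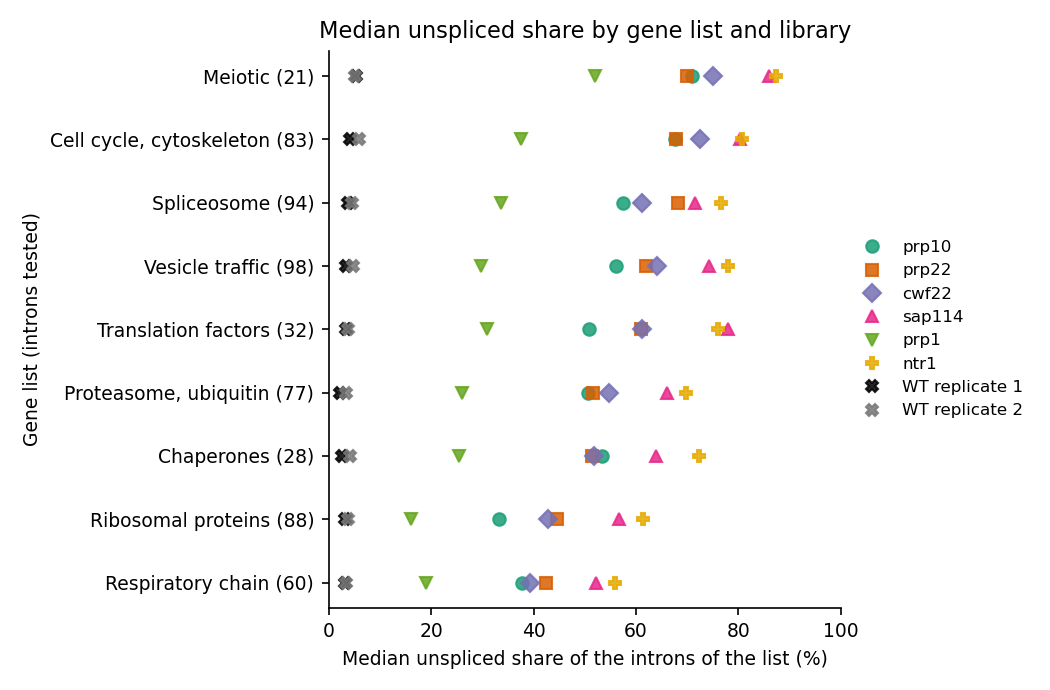
Median unspliced share in percent (horizontal axis) of the introns of each of 9 gene lists (vertical axis, with the number of introns tested) in each of the 8 libraries. Respiratory chain and ribosomal protein introns have the lowest medians in the mutants (41.3% and 43.1% over all 6), and the WT medians of all lists lie near the left edge.

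Genes often used to follow splicing in this yeast, and the mutated genes, were examined whatever their change. All 3 introns of tbp1 rose, from 33.0% ± 1.68 to 94.7% ± 7.38 in intron 1 (I 4415750 to 4416004), from 8.05% ± 0.891 to 84.6% ± 16.4 in intron 2 (I 4416066 to 4416117) and from 1.73% ± 0.566 to 71.6% ± 24.9 in intron 3 (I 4416379 to 4416448). All 5 introns of cdc2, the cyclin-dependent kinase, rose. Intron 1 in its 5′ UTR (II 1500244 to 1500285) was already at 59.2% ± 2.34 in WT and went to 87.5% ± 5.86 (edgeR adjusted p = 0.0117, a call lost without either WT library), while intron 3 (II 1500614 to 1500685) went from 2.28% ± 0.280 to 61.6% ± 23.2 (edgeR adjusted p = 1.6e-05). All 5 introns of nda3, beta-tubulin, rose, from the lowest at intron 5 (II 3964578 to 3964662, 1.48% ± 1.20 to 39.9% ± 19.2) to the highest at intron 2 (II 3965776 to 3965826, 0.694% ± 0.982 to 63.7% ± 17.1). Intron 1 of nda2, alpha-tubulin (II 4269046 to 4269135), rose from 0.606% ± 0.857 to 59.7% ± 22.2. In ubc4, a ubiquitin-conjugating enzyme, intron 1 (II 715453 to 715531) rose from 0.892% ± 0.254 to 34.7% ± 18.4 and intron 2 (II 715610 to 715980) from 11.3% ± 1.41 to 65.3% ± 13.5. Among the mutated genes, prp10 intron 1 (I 4336727 to 4336777) rose from 4.40% ± 1.35 to 75.5% ± 15.7, and the 3 introns of sap114 that were tested rose, with intron 3 (I 1173208 to 1173292) going from 1.23% ± 1.75 to 69.7% ± 24.4. The 1 annotated intron of prp22 was below 20 reads in at least 1 library. No annotated intron carried the name of cwf22, prp1 or ntr1, or of rps9.

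**Figure D4:**
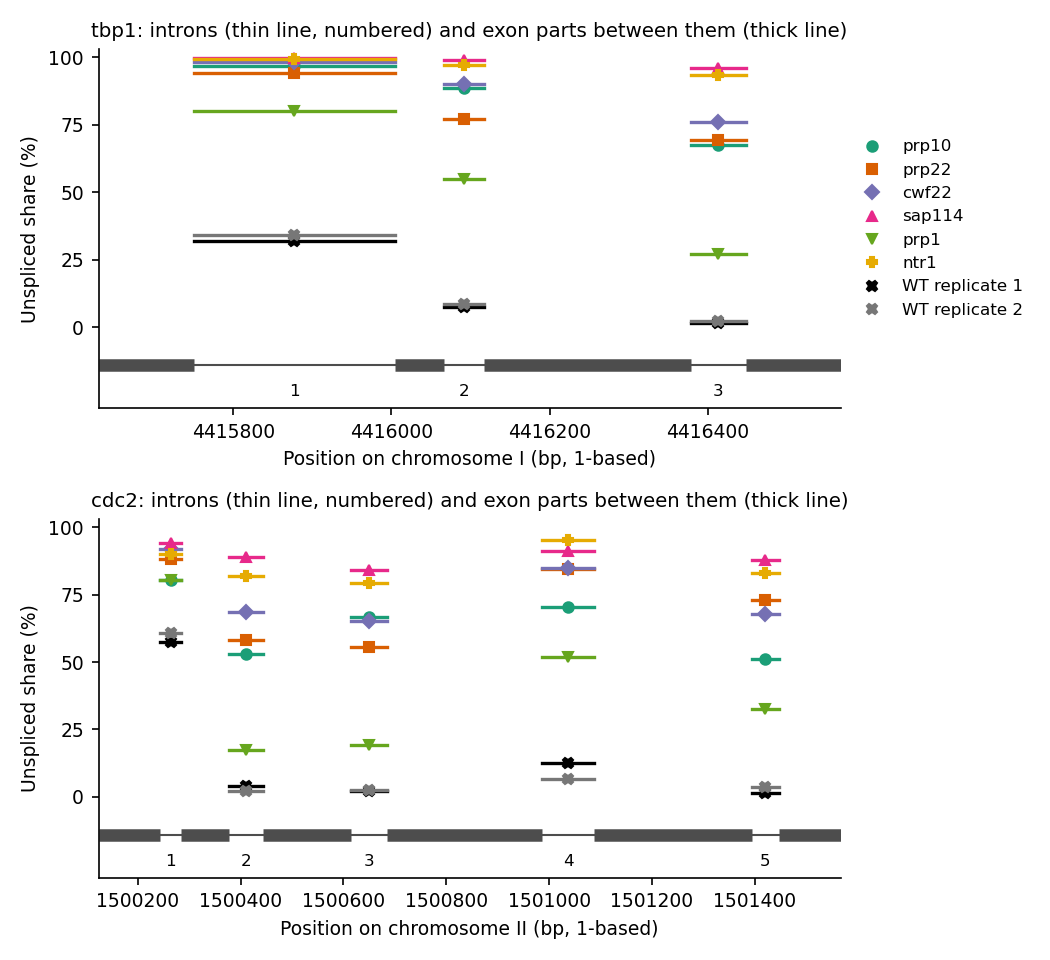
Unspliced share in percent (vertical axis) at each intron of tbp1 on chromosome I and cdc2 on chromosome II against position in bp (horizontal axis, build ASM294v2), drawn to scale. Each coloured line with its symbol is 1 library. In tbp1 the WT share falls along the gene from intron 1 (33.0%) to intron 3 (1.73%), and cdc2 intron 1 stands at 59.2% in WT.

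The fourth comparison took each strain on its own against WT. Retention was broad in every strain. In ntr1, 2484 of 2514 introns rose, led by bsd1 intron 1 (I 3492399 to 3492466) at 96.9% unspliced (95% interval 95.2 to 98.0) against 0.568% ± 0.804 in WT (SD, n = 2), SPAPB1A10.08 intron 1 at 99.8% (interval 99.0 to 100) and SPBC17A3.05C intron 1 at 96.7%. In sap114 2467 rose, led by gmh4 intron 1 at 98.3% (interval 95.1 to 99.4), pck1 intron 1 (I 2368202 to 2368256) at 99.1% against 2.63% ± 2.18, and osh42 intron 4, in an oxysterol-binding protein gene, at 97.6% against 2.18% ± 0.458. In prp22 2450 rose, led by kap114 intron 3, in a karyopherin gene, at 88.7% (interval 82.8 to 92.7) against 2.67% ± 1.42, ain1 intron 1, in the alpha-actinin gene, at 85.7% against 1.03% ± 1.46, and cnt5 intron 3 at 89.4%. In cwf22 2439 rose, led by hri2 intron 2 at 97.8% (interval 93.8 to 99.3), cys11 intron 1 at 93.5% and cki3 intron 1, in a casein kinase gene, at 91.8% against 1.43% ± 0.463. In prp10 2403 rose, led by SPAPB1A10.08 intron 1 at 95.7% (290 unspliced and 13 spliced reads), pck1 intron 3 at 98.4% and cki3 intron 3 at 93.0% against 2.93% ± 1.37. In prp1 2326 rose, led by cnt5 intron 3 at 80% (interval 73.8 to 85), SPAPB1A10.08 intron 1 at 76.2% and tup12 intron 2 at 82.4%.

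The median change in the log2 odds against WT was 3.21 in prp1, 4.69 in prp10, 4.87 in prp22, 4.99 in cwf22, 5.78 in sap114 and 6.06 in ntr1. One intron fell in the edgeR test, dbp2 intron 2 in prp1, at 98.4% (interval 97.3 to 99.1) against 99.5% ± 0.0711 (edgeR adjusted p = 0.0406), on 13 spliced reads in prp1 and 2 and 3 in WT, a call also made by limma and by Fisher's exact test against WT replicate 2 alone, and not by DESeq2 or by Fisher's exact test against both WT libraries. In the other 5 strains 0 fell in edgeR, 0 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma. Other settings chosen beforehand did call falls there. Unspliced counts alone, scaled by TMM or DESeq2 size factors of the totals, called falls in each of these 5 strains and none in prp1. Fisher's exact test against WT replicate 2 alone called a fall in cwf22 and in ntr1. The edgeR strain fits take their spread from the WT pair alone, with 1 residual degree of freedom, and assume that a mutant library varies as the WT libraries do. The estimated prior degrees of freedom were infinite, so each intron took the spread fitted across introns and not its own. Unspliced counts scaled by TMM on unspliced reads gave 276 rises and 367 falls in prp10, 276 and 385 in prp22, 303 and 366 in cwf22, 343 and 399 in sap114, 116 and 217 in prp1 and 435 and 411 in ntr1.

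The fifth comparison asked which introns set one strain apart from the other mutants. The prp1 strain retained less RNA than the other 5 at 1168 introns, in the edgeR test with the spread between strains. The largest differences were at rtf2 intron 1 (I 653179 to 653221), with 24.3% in prp1 (interval 17.9 to 32) against 71.4% to 90.4% in the other 5 mutants, and at SPAC4A8.14 intron 1 (I 2577578 to 2577619), with 20.6% (interval 16.7 to 25.3) against 69.9% to 87.5%. The edgeR adjusted p was 0.0218 for both. In this test 0 introns rose in prp1 and 0 rose or fell in each of the other 5 strains, with 3 introns at an unadjusted p under 0.05 in prp10, 1 in prp22, 2 in cwf22, 60 in sap114, 162 in ntr1 and 1536 in prp1. DESeq2 called 1339 introns in prp1 and 0 in the other strains, and limma called 897 in prp1, 2 in ntr1 and 0 in the rest. Without the sap114 library the prp1 count is 751.

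No intron passed in the other 5 strains, but this does not show that no intron differs. Chance gives about 1 in 20 of the 2514 introns at the unadjusted threshold above. The counts of prp10, prp22, cwf22 and sap114 fell short of that, and the count of ntr1 did not. For those 4 strains the test was therefore stricter than its threshold. The 2 largest differences of each of the 5 strains are given by size. In ntr1 they were at par1 intron 4 (III 1477280 to 1477331), with 80.7% against 20.8% to 48.2% in the other mutants, and png2 intron 2 (II 1121739 to 1121785), with 73.6% against 8.87% to 36.4%. In sap114 they were at SPAC1B3.02C intron 1, with 80.9% against 8.11% to 60.4%, and vti1 intron 5, with 81.3% against 23.1% to 63.8%. In prp10, ini1 intron 3 was at 93.5% against 28.8% to 89.4% and nda2 intron 1 at 33.6% against 30.9% to 82.6%. In prp22, SPAC644.09 intron 3 was at 16.9% against 18.5% to 64.8% and mrp11 intron 1 at 56.2% against 14.2% to 46.3%. In cwf22, prp17 intron 3 was at 25% against 23.6% to 79.2% and smf1 intron 1 at 53.4% against 17.2% to 39.0%.

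After centring on each library's median, an alternative chosen after the data were seen, the edgeR test called 0 introns in any strain, prp1 included, with between 29 (cwf22) and 304 (prp1) introns at an unadjusted p under 0.05. The lower end of that range is again below the chance level, so these 0 calls do not show that no intron differs. With centring and the spread of the WT pair, 28 introns were called in prp10, 74 in prp22, 101 in sap114, 195 in ntr1, 380 in prp1 and 0 in cwf22, but that spread comes from 2 libraries of one strain and no intron is taken as specific to a strain from it.

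The sixth comparison measured how alike the strains were. Changes were correlated between all pairs of strains. Across introns, which are not independent replicates, Pearson correlations of the change in log2 odds for the 15 pairs of strains ran from 0.806 (prp1 and ntr1) to 0.894 (sap114 and ntr1), with a mean of 0.855, and Spearman correlations from 0.786 to 0.890. All strains share the WT libraries, and unchanged strains simulated against them gave a mean correlation of 0.387. The covariance ran from 1.47 to 3.18 against 0.314 in the simulation. With a different WT library for each strain of a pair the correlations ran from 0.538 to 0.728. Both settings deal with noise in the WT libraries only. The WT level of each intron is still subtracted from every strain and adds to the correlation. The log2 odds themselves, without WT subtracted, correlated between mutants at 0.775 to 0.902. They carry the level that each intron has in WT as well. Their Spearman correlations with WT replicate 2 ran from 0.453 (ntr1) to 0.739 (prp1), and that between the WT libraries was 0.771. In all 6 strains 2271 introns rose, among them those of cnt5, pck1 and tup12 named above, and 13 introns rose in no strain. The overlap of rising introns per pair ran from 2291 to 2457, and lists without any relation would share from 2223 to 2438.

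The seventh comparison asked whether intron length, sequence or position went with retention. Long introns had higher unspliced shares than short ones in WT and mutants alike. How unspliced reads were counted is not given in the sources used here, so that a dependence of the share on length cannot be separated from the counting. The upper tercile, above 84 nt, had a median share of 11.1% in WT and 77.7% in the mutants, and the lower tercile, up to 52 nt, had 3.44% and 59.1%. Introns in 5′ UTRs had 19.3% in WT and 83.0% in the mutants, over 47 introns. The change in log2 odds relative to all introns was −0.09 for the upper tercile (exact permutation p = 0.25) and −0.01 for the lower tercile (exact p = 1.0). First introns had 0.13 (exact p = 0.0357), internal introns −0.24 (exact p = 0.0357) and genes with a single intron 0.16 (exact p = 0.0357). In percentage points relative to all introns the sign turned for first introns (−0.00890) and for the upper tercile of length (6.47). Introns with the 5′ splice site GTAAGA had −0.26 and those with GTATGT 0.17 (exact permutation p = 0.0357 for each). Those ending in AAG had −0.31, and those with the inferred branch site CTGAC 0.34 (exact permutation p = 0.0357 for each). None of the 29 features passed BH adjustment, where the lowest BH p was 0.148. Across 2514 introns, Spearman's rho between length and log2 odds was 0.356 and 0.421 in the WT libraries and between 0.265 (prp10) and 0.408 (prp1) in the mutants.

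The eighth comparison took the sum of spliced and unspliced reads per gene as a measure of transcript level for genes with introns. Total reads of aco1, aconitase, and atf1, a stress-response transcription factor, rose in the mutants, though their spliced reads alone did not pass, with an edgeR adjusted p of 0.00288 for aco1 and a log2 change of 2.58 for atf1 (standard error 0.42, edgeR adjusted p = 0.00754). Total reads of isn1, an IMP nucleotidase, fell by 2.23 on the log2 scale (standard error 0.23, edgeR adjusted p = 0.00288), those of mvp1, a sorting nexin, fell by 1.71 and those of mmi1, which marks meiotic mRNAs for removal, fell by 1.52 (edgeR adjusted p = 0.0338). The log2 change of min8 was −1.67 (edgeR adjusted p = 0.0452). In all, 226 genes rose and 116 fell of 2272 tested in edgeR with TMM, with 710 at an unadjusted p under 0.05. These genes were chosen after their values were seen. The calls depend on both WT libraries, since without WT replicate 1 there were 0 calls in edgeR and 480 genes at an unadjusted p under 0.05, and without replicate 2 there were 0 and 433. An intron adds reads of its own when retained, and with spliced reads alone 2 genes rose and 2 fell of 1977, with 531 at an unadjusted p under 0.05. In that setting aco1 was at 0.31 and atf1 at −0.06, while isn1 stayed at −2.33 (edgeR adjusted p = 0.0186), mvp1 was at −1.83 (edgeR adjusted p = 0.0834) and mmi1 at −1.76 (edgeR adjusted p = 0.0637). The change of min8 shrank there to −0.62 (edgeR adjusted p = 0.452).

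By list, 10 of 35 respiratory chain genes fell in these totals (15 adjusted over the list alone), with cox7 at −0.86, and 2 rose (2 adjusted over the list alone), with cox6 at 0.77. Totals hold the reads of retained introns, so a list that retains less can fall relative to other genes without a fall in spliced mRNA. Relative to reads across gaps under 30 nt, spliced reads stood at 0.697 of WT in respiratory chain introns and 0.522 in the typical tested intron. List counts with spliced reads alone are not given here, and in that setting 2 genes fell of 1977. Of 74 ribosomal protein genes 8 rose and 10 fell (9 and 12 adjusted over the list alone), from rps3002 at −0.60 to rps1001 at 1.29. Of 36 proteasome and ubiquitin genes 3 rose and 7 fell (3 and 10 adjusted over the list alone), from rpn3 at −0.82 to rpt4 at 1.17. In the cell cycle list 7 of 76 rose and 4 fell (8 and 5 adjusted over the list alone), with cut6, an acetyl-CoA carboxylase, at 1.83 and arc2, of the Arp2/3 complex, at −0.67. Of 68 spliceosome genes 2 rose and 4 fell (2 and 3 adjusted over the list alone), of 65 vesicle traffic genes 4 and 2 (4 and 2 adjusted over the list alone), and of 19 translation factor genes 1 and 2 (2 and 3 adjusted over the list alone). Of 16 chaperone genes 1 rose, aha1, a partner of Hsp90, at 1.26 (1 adjusted over the list alone), and of 31 meiotic genes 0 changed in edgeR (0 adjusted over the list alone), with 2 rises and 3 falls at an unadjusted p under 0.05. The genes rpn501, rpn502 and rpl1802 were also called but have near-identical copies, so that their values are uncertain and are left out of the list counts.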

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

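The tests of prp1 against a WT library and against libraries of like depth and the count of splits of the libraries were chosen after the results were seen, while the test of mixed cells was set before its result, as was a test of depth by thinning that is set aside because thinning cannot move a mean share.

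The prp1 library had the lowest unspliced share of the mutants, with a median of 37.5% against 62.4% for the next lowest, prp10, and 1168 introns less retained in the test of the difference between strains, a number that was 0 after centring on library medians, while a test for a library far from the other 5 did not single out its median share (gap to the next over the range of the 6, 0.570). Read depth does not account for it, since the 2 mutant libraries next to prp1 in total reads, cwf22 (909213) and prp22 (1279618, prp1 1139031), had medians at least 29.4 percentage points higher. An exchange with a WT library is also excluded, since its median lay 31.9 percentage points above the higher WT median. RNA of WT cells mixed into the culture cannot be excluded: the WT fraction it implies was 0.257 over 82 introns more than 90% unspliced in the other mutants and 0.564 over 593 introns between 50% and 80%, a difference of 0.307 (bootstrap SD 0.0123), but total reads over gap reads rose by 1.74 log2 units in the first set and by 0.59 in the second, so that a mixture need not give one value. A milder block of splicing by this allele may also remain, which 1 library per strain cannot separate from a difference in how that culture was shifted.

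The 2437 introns that rose in the mutants as a class were set against all 28 splits of the 8 libraries into 6 and 2. Only 1 split, the real one, gave as many, and the highest count of any other split was 0. This share of 0.0357 excludes chance in the grouping at the 0.05 level and no further, since it is the smallest that 28 splits can give and each other split puts WT among the mutants.

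Of 47 sets of mutant values examined for a library far from the other 5, 3 had one, where chance gives about 1 in 20. Introns in the middle length tercile lay at −0.48 log2 units relative to all introns in prp10, against −0.31 to −0.22 in the other mutants. Introns with a long distance from the inferred branch site to the 3′ splice site lay at 0.46 in cwf22, against 0.28 to 0.32. Introns with the 5′ splice site GTATGT lay at −0.15 in prp10, against −0.03 to 0.04.

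Reads in 2 classes of junction that no comparison above used were higher than in WT as a percentage of annotated spliced reads, which themselves stood at 0.657 of WT relative to gap reads. Reads that the authors classed as joining known splice sites in another pairing came to 1.53% ± 0.0908 (SD, n = 6) of annotated spliced reads in the mutants. In WT they came to 1.22% ± 0.0475 (SD, n = 2; two-sided exact permutation p = 0.0357). Of these reads 76.0% lay in 3 junctions, rps3 intron 1, rpl701 intron 1 and cpc2 intron 2. All 3 match introns of the reference annotation used here at both ends. Most of the class is thus ordinary splicing by that annotation, and the higher percentage does not show more alternative pairing. Without these 3 junctions the mutants were lower, at 0.330% ± 0.0306 (SD, n = 6) against 0.364% ± 0.0191 (SD, n = 2), and relative to gap reads the whole class stood at 0.818 ± 0.155 (SD, n = 6) of WT (two-sided exact permutation p = 0.179). Reads across gaps under 30 nt, too short for a typical intron of this yeast, came to 3.66% ± 0.728 (SD, n = 6) of annotated spliced reads in the mutants and 2.32% ± 0.0126 (SD, n = 2) in WT (two-sided exact permutation p = 0.0714), which sets the same reads against each other as the ratio of 0.657 does.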

How the results depend on the processing

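The alternatives with centring, with TMM on unspliced counts, with spliced reads alone and with length-scaled unspliced reads were chosen after the data were seen, and the others before. No paired analysis was possible because the mutant strains have replicate number 1 only and share fewer than 2 numbers with WT. The comparison of the 5′ with the 3′ side of introns could not be made, since 1 unspliced count is given per intron. Depth limits how many introns could be tested, 2514 of 5144 at 20 reads in every library and 1400 at 50, and WT replicate 1 has a median of 59.0 reads per tested intron. The strain fit, with 1 residual degree of freedom, recovered 10% of simulated 2-fold changes, where few introns changed and the mutant library varied like WT. Of 245 alternative values of counts and library-wide results 198 stayed within the bounds set. These include counts of introns apart in prp10, prp22, cwf22, sap114 and ntr1 that were 0 in both settings, which says little about stability. Of 2486 values for single introns, genes and features 2363 kept direction and side of the threshold, 72 lost a call, 31 gained one and 20 changed sign. Where nothing else is said, the cause was not tested.

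Fewer introns are tested at a minimum of 50 reads, which gave 1382 rises in prp10, 1387 in prp22, 1384 in cwf22, 1389 in sap114, 1361 in prp1, 1392 in ntr1, 1369 in the class and 760 introns apart in prp1. A minimum of 1 read tests more, with 3721 in prp22, 3746 in sap114, 3828 in ntr1 and 3835 in the class. TMM on unspliced counts takes out the rise common to all introns by construction, and left 276 rises in prp10, 276 in prp22, 303 in cwf22, 343 in sap114, 116 in prp1, 435 in ntr1 and 332 in the class, with 1, 2 and 16 introns apart in prp10, prp22 and prp1, all of them higher, where the 1168 of prp1 were lower. Centring does likewise, with 215 rises in the class and 0 introns apart in prp1. Centring with the spread of the WT pair gave 28 introns apart in prp10, 74 in prp22, 101 in sap114, 380 in prp1 and 195 in ntr1. Unspliced counts with TMM of totals gave 759 introns apart in prp1, and limma gave 2 in ntr1. Leaving out 1 library at a time gave 751 to 1365 introns apart in prp1, an overall difference of 57.4 to 66.1 percentage points and 0 to 449 genes changed in total reads, with 0 without either WT library. Spliced reads alone gave 4 such genes and length-scaled unspliced reads 61.

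The median log2 change without 1 WT library ran from 4.59 to 4.76 in prp10, 4.78 to 4.89 in prp22, 4.88 to 5.07 in cwf22, 5.69 to 5.83 in sap114, 3.07 to 3.22 in prp1 and 5.95 to 6.07 in ntr1. The mean correlation between strains was 0.630 with a different WT library for each strain. In percentage points, values relative to all introns changed sign for middle (−3.47) and long introns (6.47), middle branch distance (−1.37), middle and high GC (1.25 and 3.18), first introns (−0.00890), GTAAGC (0.0131), CAG (0.158), CTAAC (−0.345), no branch site found (1.33), 5′ UTR (5.46) and coding introns (−0.385). With a pseudocount of 1 they did so for middle and high GC (0.0327 and 0.0396), GTATGA (0.0156), CAG (0.0267) and CTGAT (−0.0255). Unspliced counts alone gave −0.0194 (TMM of totals) and −0.0193 (DESeq2 size factors) for mug161 intron 4, and spliced reads alone −0.0645 for atf1.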

Other observations

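The tests on random lists, unspliced rise and spliced reads of ribosomal protein genes were chosen after the results were seen, while those of WT read numbers and of neighbouring introns were set before theirs.

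Spliced reads can be set against a reference assumed not to depend on splicing, the reads across 179 gaps under 30 nt, of which 114 have a length that is a multiple of 3. Relative to these, annotated spliced reads in the mutants stood at 0.657 ± 0.149 (SD, n = 6) of WT, from 0.517 in sap114 to 0.921 in prp1 (two-sided exact permutation p = 0.0357). The typical tested intron kept 0.522 of its spliced reads. By gene list the introns kept 0.936 in ribosomal protein genes, 0.697 in the respiratory chain, 0.652 in translation factors, 0.646 in chaperones, 0.602 in proteasome and ubiquitin genes, 0.542 in the spliceosome, 0.506 in vesicle traffic, 0.492 in the cell cycle list and 0.386 in meiotic genes. Their percentiles among random lists matched on read count were, in the same order, 100, 99.97, 97.9, 96.2, 92.2, 86.8, 31.1, 5.38 and 0.460, without adjustment for the 9 lists. Nor was allowance made for introns of one gene being alike. Among introns chosen after their values were seen, spliced reads relative to gap reads changed by −4.33 log2 units at pck1 intron 3 (3 reads in prp10, 32 in prp22, 8 in cwf22, 5 in sap114, 135 in prp1 and 6 in ntr1, 164 and 316 in WT) and by 0.13 at srp2 intron 3, in the gene of an SR splicing protein (188, 238, 185, 252, 323 and 259 in the same order, 129 and 278 in WT). The 3 most abundant gaps hold 47.3% of gap reads, and without them the mutants stood at 0.681 ± 0.144 (SD, n = 6) of WT.

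The gene mfm2, which encodes the M-factor mating pheromone, had 3 reads over both WT libraries and 297 over the 6 mutants, a ratio of rates of 17.2 (exact 95% interval 5.82 to 83.7 from counting error). Its spliced reads were 13 in prp10, 21 in prp22, 15 in cwf22, 37 in sap114, 48 in prp1 and 14 in ntr1 against 1 and 2 in WT. The mating type of the strains is not given in the sources used here, and no test of it was made.

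Ribosomal protein introns showed lower unspliced shares than other introns in all 6 mutants, with a median of 43.1%. They were lower in both WT libraries too, with medians of 3.22% and 3.75% against 4.67% and 5.60% for all tested introns. The difference of the list in its change did not pass adjustment (exact permutation test, BH p = 0.107). Read count and intron length do not account for the smaller rise of their log odds against WT. Of 10000 random lists matched on both and drawn intron by intron, 0 changed as little. The lower share itself was not tested in this way. These introns did not gain less unspliced RNA, as their rise in unspliced reads over gap reads was 0.17 log2 units above that of all tested introns (bootstrap SD 0.07). Their spliced reads lay at percentile 100 of random lists matched on read count, but this follows from a lower share once unspliced reads rise as much as elsewhere, so it does not decide whether spliced mRNA of these genes was kept from before the shift, and that explanation stays open.

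Introns of the same gene resembled each other in the mutants. Over 653 genes with at least 2 tested introns, the within-gene correlation of log odds, adjusted for length, was 0.429 in prp1, 0.577 in prp10, 0.634 in cwf22, 0.636 in prp22, 0.714 in sap114 and 0.804 in ntr1 against 0.231 and 0.185 in WT. Few unspliced reads in WT are not enough to account for the gap, since mutant values redrawn at the WT level and depth still gave 0.311 or more. Neighbours with an exon of at least 300 nt between them correlated at 0.414 or more in each mutant (197 pairs). Reads shared across shorter exons are therefore not enough either. Read length and the counting of unspliced reads are not given, so reads shared across such long exons cannot be excluded. A candidate explanation is that, once splicing is blocked, the share follows how much new and old RNA each gene has, which no test here addressed.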
